A study of Mus musculus with 212 samples.

How the data were processed

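Gene-level RNA-seq values were deposited for 212 libraries of mouse skin fibroblasts, WT or with Bmal1 knocked out (Bmal1KO). Per the labels, confluent C57BL/6 cultures received 100 nM dexamethasone for 15 min, were then kept in HEPES-buffered medium in constant darkness, and were first harvested 48 h after the dexamethasone. RNA came from 3 wells per time point and genotype. Whether the wells were pooled, and whether more than 1 cell preparation per genotype was used, is not given in the sources used here. The libraries form 10 time courses with 1 library per time point. The courses named AM and PM have 17 time points each (CT0 to CT48, every 3 h) and the courses at 27, 32 and 37 °C have 24 time points each (CT0 to CT46, every 2 h). The labels do not say what AM and PM stand for.

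The deposited values are FPKM (fragments scaled to transcript length and to the number of mapped reads), per the column names. The authors selected poly(A) RNA and made stranded libraries that were read from a single end. The submitters' processing notes name TopHat2 2.1.0, TopHat, Cuffdiff and the mouse build GRCm38. The annotation, the alignment settings and the scaling between libraries are not given in the sources used here. The table held 47631 genes, of which 33393 were above 0 in any library. Symbols and coordinates came from an annotation of the same build, and 47217 gene IDs matched it. No column was left out.

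The deposited table holds no read counts, so depth was estimated from the FPKM that 1 read gives. For 1345 genes with a single annotated transcript of at least 1500 bp, detected in 2 to 25% of libraries, 93.8% of the low values lay within 0.15 of a whole number of reads. The estimated depth ran from 3.31 to 32.35 M reads, with a median of 23.58 M. In every library 10278 genes were above 1 FPKM. Since the depth is an estimate, no counting intervals were computed.

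Values were transformed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the libraries of a fit were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), using lmFit and eBayes with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Each course had its own intercept, linear time term and 24 h cosine and sine. Level contrasts compared the intercepts, two-sided. A gene was called changed at an adjusted p under 0.05 and at least a 2-fold difference, and for the genotype contrasts also the same sign in each part (AM and PM, or the 3 temperatures). A gene was called rhythmic at an adjusted p under 0.05 in the moderated F test of the cosine and sine terms. The shared fits tested the cosine and sine averaged over courses, and the opposite fits tested the contrast of AM against PM, which is large when the courses peak 12 h apart by time label. Amplitudes are log2 values from mid-level to peak. The interaction contrast was the change from 37 to 27 °C in Bmal1KO minus that in WT. The number of preparations per genotype is not given, so the p-values measure the spread between libraries of a course and not between cell preparations or animals.

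The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Named are all core clock genes, the 8 genes with the largest rise and the 8 with the largest fall per level comparison (predicted genes and pseudogenes left out of the naming only), up to 4 members per list with the largest change, and the 10 genes with the smallest p per rhythm fit. Some genes that this rule picks are not reported here, though counts and list tests include them. The 28 lists cover the core clock, E-box targets of CLOCK and BMAL1, REV-ERB and ROR targets, glucocorticoid response, mitosis and S phase, cold-inducible genes, heat shock, the unfolded protein response, redox enzymes and peroxiredoxins, cholesterol synthesis, extracellular matrix, contractile and YAP targets, interferon response, NF-kB and inflammation, p53 targets, immediate early genes, hypoxia and glycolysis, the mitochondrial genome, ribosomal proteins, ETS factors, sex-linked genes, and markers of keratinocytes, endothelium, macrophages, adipocytes, muscle, melanocytes and Schwann cells, and cartilage and bone. Lists with at least 3 tested members were tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. In the shared rhythm fits, list counts were compared with other genes by one-sided Fisher exact tests, and the same tests in the opposite fits were added after the data were examined.

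In addition, time labels were permuted within courses (100 orders), libraries were regrouped at random (100 splits), 14 periods from 8 to 36 h were scanned, and peak times were compared between courses for genes at an unadjusted p under 0.05 in both. A common clock gene period was fitted per course on a grid from 18 to 36 h in steps of 0.25 h, with a jackknife SE over time points. The fits were checked against limma's own functions and tested on simulated data. Alternatives were a pseudocount of 0.1 FPKM, no filter, median-of-ratios scaling, no or quadratic time terms, no CT00 libraries, a cosine fitted to ranks, the time label as a block, eBayes without trend, single courses, a smaller set of clock genes and a stricter p for peak times. Alternatives without the CT14 libraries at 27 °C, without the WT AM CT36 library, without 5 Bmal1KO libraries at 37 °C, with terms for 12 h blocks, and the genotype difference in the contrast of AM against PM were added after the data were examined. Depth and tables were computed with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.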

Results

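Transcript levels were measured by poly(A) RNA-seq in 212 libraries of dexamethasone-treated mouse skin fibroblasts, WT or lacking the clock gene Bmal1 (gene symbol Arntl). The AM and PM courses of both genotypes hold 68 libraries, and those at 27, 32 and 37 °C, with 24 time points each, the others. Each time point has 1 library, so values are given as the mean and SD over the 17 or 24 time points of a course. Estimated depth per course had a median between 18.74 M reads in WT AM and 28.04 M in WT at 32 °C. The shallowest library was WT AM at CT36 with 3.31 M reads. The series asks, by its title, whether circadian rhythms persist without Bmal1.

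Arntl itself (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, GRCm38) was read at similar levels in both genotypes in AM and PM. It averaged 7.29 ± 1.61 FPKM (SD, n = 17) in WT AM and 6.56 ± 0.359 in Bmal1KO AM, and 7.36 ± 1.45 in WT PM and 7.31 ± 0.379 in Bmal1KO PM. At 27 °C it was higher in Bmal1KO (7.87 ± 0.847 against 5.11 ± 1.39), at 32 °C it averaged 7.14 ± 0.428 against 6.17 ± 1.11, and at 37 °C 5.79 ± 0.53 against 6.14 ± 1.57. The deleted part of the gene is not given in the labels, so this value does not check them. Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), separated the genotypes. It averaged 125 ± 7.55 FPKM in Bmal1KO AM against 2.74 ± 1.03 in WT AM, and 124 ± 5.88 in Bmal1KO PM against 3.81 ± 0.935 in WT PM. The pair of libraries labelled CT14 at 27 °C went against their labels, with 109 FPKM in the WT library and 3.87 in the Bmal1KO library.

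**Figure D1:**
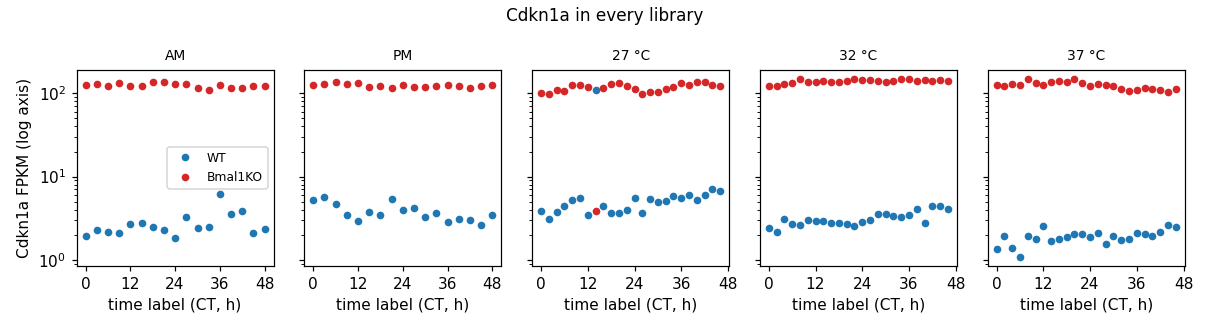
Cdkn1a level (FPKM, log axis) against time label (CT, h) in the 10 time courses, 1 library per point, WT and Bmal1KO in separate colours. The genotypes are apart in every course except for the libraries labelled CT14 at 27 °C, which read 109 FPKM (WT) and 3.87 FPKM (Bmal1KO).

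The genotype comparison in AM and PM asked which transcripts differ in level apart from rhythm. The largest rises in Bmal1KO were in Anxa8 (log2 fold change 6.01 ± 0.02 SE), the iron carrier gene Trf (5.61), Myrf (5.56), the angiotensinogen gene Agt (5.37), Gdf10 (5.18), Tmeff2 (5.05), Vsnl1 (4.97) and Cdkn1a (4.91 ± 0.04), each higher in Bmal1KO at 34 of 34 time points. The largest falls were in the growth factor binding protein gene Igfbp5 (-7.52 ± 0.05), the tendon gene Tnmd (-7.38), Itm2a (-7.28), the retinoic acid binding protein gene Crabp1 (-6.6), Art3 (-6.55), the developmental regulator Zic1 (-6.35), Arhgdib (-5.73) and the body position gene Hoxa9 (-5.44), each higher in Bmal1KO at 0 of 34. Agt averaged 489 ± 56.5 FPKM in Bmal1KO AM and 12.2 ± 1.64 in WT AM, and Igfbp5 averaged 0.911 ± 0.332 and 442 ± 88.4. For genes near 0 in 1 genotype the size of the fold depends on the pseudocount. Of 13307 genes tested, 933 were higher and 1002 lower in Bmal1KO. The adjusted p was 4.03e-67 for Cdkn1a and 4.95e-82 for Anxa8. An adjusted p under 0.05 was reached by 11487 of the genes tested, so the calls rest mainly on the 2-fold limit. These p-values measure the spread between libraries of a course and not between cell preparations.

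Among the gene lists, 11 of 12 p53 targets rose in Bmal1KO and 0 fell (adjusted p = 3.02e-06, and 3.55e-05 with an estimated correlation). Besides Cdkn1a they included Ccng1 (3.28), Phlda3 (2.99) and Mdm2 (2.43), the last a negative regulator of p53. Of 21 mitosis and S phase genes 16 fell and 0 rose (adjusted p = 3.24e-08, and adjusted p = 0.0523 with an estimated correlation), led by Ccna2 (-2.74), Top2a (-2.53), Mki67 (-2.16) and Birc5 (-1.78). Of 24 ribosomal protein genes 11 rose and 1 fell (adjusted p = 7.48e-06, and adjusted p = 0.277 with an estimated correlation), with Rps19 at 1.86 and Rpl19 at 1.53. Of 20 cholesterol synthesis genes 3 fell (adjusted p = 0.000519, and adjusted p = 0.369 with an estimated correlation), with Cyp51 at -1.17 and Sc5d at -1.12. Of 10 contractile and YAP target genes 5 fell (adjusted p = 0.00454, and adjusted p = 0.277 with an estimated correlation), with Ankrd1 at -3.48 and Tpm2 at -1.65. All 3 tested adipocyte markers rose (adjusted p = 0.0482, and adjusted p = 0.21 with an estimated correlation): Fabp4 (2.42), Lpl (1.27) and Pparg (1.22). Counts of changed members adjusted over the list alone were equal to these in every list.

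The other lists did not pass their test in AM and PM. The interferon response had 0 higher and 4 lower of 13 (adjusted p = 0.0502), with Ifi44 at -2.87. The keratinocyte markers had 2 lower of 3 (0.0606), immediate early genes 0 changed of 9 (0.0786), and mitochondrial genome transcripts 0 changed of 7 (0.0786). The unfolded protein response had 3 lower of 17 (0.422), glucocorticoid response genes 4 higher and 2 lower of 15 (0.495), redox genes 3 higher and 2 lower of 22 (0.495, with Gpx3 at -2.49) and cold-inducible genes 0 changed of 5 (0.495). Heat shock genes had 4 lower of 15 (0.563), extracellular matrix genes 3 higher and 3 lower of 21 (0.563, with the protease genes Mmp3 at -5.22 and Mmp13 at -3.19), NF-kB targets 3 higher and 1 lower of 12 (0.664) and hypoxia and glycolysis genes 1 lower of 15 (0.664). ETS factors had 3 lower of 15 (0.752), macrophage markers 1 lower of 3 (0.774), and sex-linked genes 0 changed of 4 (0.664). The other marker lists had under 3 tested members: the endothelial gene Kdr stood at -1.74 and Tek at 0, the melanocyte gene Mlana at -2.84 and the cartilage gene Sox9 at 0.43, and 0 muscle markers were tested.

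Clock transcripts moved in both directions. Of 22 core clock genes 4 were higher and 4 lower in Bmal1KO (adjusted p = 0.757), of 15 E-box targets of CLOCK and BMAL1 3 were higher and 5 lower (0.664), and of 5 REV-ERB and ROR targets 2 were higher (0.757). Higher were Npas2, a partner of BMAL1 (1.4 ± 0.05), the repressors Cry1 (1.88 ± 0.02) and Cry2 (1.12 ± 0.02), and Usp2 (1.17 ± 0.07). Lower were Per3 (-1.77 ± 0.04), Nr1d1 (-1.6 ± 0.03) and Nr1d2 (-2.89 ± 0.03), which encode the REV-ERB receptors, and Hlf (-3.19 ± 0.09). Arntl stood at -0.05 ± 0.02 (adjusted p = 0.0564).

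In the temperature series the same contrast gave 735 higher and 873 lower genes of 13032. Anxa8 (7.26 ± 0.15), Gdf10 (5.83), Myrf (5.8), Stxbp2 (5.34), Cdkn1a (4.84), Psrc1 (4.83), Trf (4.82) and Clca3a1 (4.76) led the rises, each higher at 71 of 72 time points. Tnmd (-7.49 ± 0.15), Crabp1 (-6.61), Zic1 (-6.42), Itm2a (-6.39), Art3 (-6.28), Igfbp5 (-5.69), Prl2c2 (-5.56) and Plxdc2 (-5.53) led the falls, each higher at 1 of 72, which was CT14 at 27 °C. Of 1800 genes called in AM and PM and tested in both, 99.3% had the same sign here, and 1236 were called in both with the same sign, against 110 by chance. The p53 targets again had 11 of 12 higher (adjusted p = 4.34e-06). With an estimated correlation this was an adjusted p = 0.568, and without the CT14 libraries at 27 °C it was 4.8e-06 with an estimated correlation. Of 20 cholesterol synthesis genes 14 fell (adjusted p = 5.99e-07), of 22 ribosomal protein genes 5 rose (1.17e-06), of 20 mitosis and S phase genes 5 fell (0.00183) and of 13 interferon response genes 4 fell (0.00663). With an estimated correlation these were adjusted p = 0.589, 0.568, 0.625 and 0.695. Clock genes called here were Cry1 (1.65) and Usp2 (1.22), higher, and Per3 (-1.76), Nr1d2 (-2.11), Dbp (-1.08), Hlf (-3.1) and Ciart (-1), lower.

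The temperature comparisons asked how levels depend on culture temperature. Each temperature has 1 course per genotype, so temperature cannot be separated from the culture or run. From 37 to 27 °C the median over all genes moved by 0.21 in WT and 0.207 in Bmal1KO (log2), and to 32 °C by 0.132 and 0.129, so the split of calls into higher and lower depends on the scaling. In WT, 1089 genes were higher and 684 lower at 27 °C as deposited, and 604 and 997 with median-of-ratios scaling. In Bmal1KO the counts were 1001 and 532 as deposited, and 573 and 811 with that scaling. In both genotypes 609 genes rose and 308 fell together, 917 against 112 by chance.

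At 27 °C many inflammatory and some matrix transcripts fell. In WT, 6 of 12 NF-kB and inflammation genes fell (adjusted p = 2.47e-07, and 0.00157 with an estimated correlation), led by complement C3 (-3.51 ± 0.06), Cxcl5 (-2.31) and Icam1 (-1.74). In Bmal1KO 8 of 12 fell (9.51e-11, and 4.47e-05 with an estimated correlation), led by the acute phase gene Saa3 (-4.81 ± 0.08) and C3 (-3.89). Interferon response genes fell in WT (8 of 13, adjusted p = 1.01e-05) and in Bmal1KO (8 of 13, 3.82e-07), with Oasl2 at -2.6 and -2.91, and the adjusted p with an estimated correlation was 0.412 and 0.195. Of 20 extracellular matrix genes 5 fell in WT (3.67e-06), among them Col6a3 (-2.29) and Col1a1 (-1.29), and in Bmal1KO 5 fell and 3 rose (0.000514), with Col6a3 at -3.09 and Mmp13 at 1.81. The adjusted p with an estimated correlation was 0.0684 and 0.156. Immediate early genes fell in Bmal1KO (4 of 8, adjusted p = 4.98e-05, and 0.00478 with an estimated correlation), with Jun at -2.19 and Egr1 at -1.89, and in WT their test gave an adjusted p of 0.117. In Bmal1KO 2 of 3 adipocyte markers fell (0.00907, and adjusted p = 0.0893 with an estimated correlation), with Lpl at -2.5, while the list gave 0.179 in WT, where Lpl fell by 3.44. The difference between genotypes had an adjusted p of 3.88e-06 for immediate early genes and 0.157 for adipocyte markers. With median-of-ratios scaling the lower counts, WT and then Bmal1KO, were 8 and 9 for NF-kB and inflammation, 11 and 11 for interferon response, and 9 and 6 for extracellular matrix (0 and 2 higher), and in Bmal1KO 6 for immediate early genes and 2 for adipocyte markers.

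Transcripts of some cold-inducible and cholesterol synthesis genes rose at 27 °C. The RNA-binding protein genes Cirbp (2.32 ± 0.05 in WT and 2.71 ± 0.05 in Bmal1KO) and Rbm3 (2.09 and 1.39) rose at 24 of 24 time points, and the list passed in WT (3 of 5 higher, adjusted p = 0.0292, and adjusted p = 0.283 with an estimated correlation) and Bmal1KO (2 of 5, 0.0108, and adjusted p = 0.156 with an estimated correlation). Of 20 cholesterol synthesis genes 5 rose in WT (0.0292, and adjusted p = 0.693 with an estimated correlation) and 5 in Bmal1KO (0.00907, and adjusted p = 0.917 with an estimated correlation), with Insig1 at 2.33 and 1.8. In WT 7 of 15 E-box targets rose (0.0469, and adjusted p = 0.412 with an estimated correlation), led by Bhlhe41 (1.88), Ciart (1.82), Cry1 (1.4) and Bhlhe40 (1.32), and their interaction with genotype had an adjusted p of 0.0529 (0.025 without the CT14 libraries at 27 °C, and 0.349 with an estimated correlation). With median-of-ratios scaling the higher counts, WT and then Bmal1KO, were 2 and 2 for cold-inducible genes and 3 and 4 for cholesterol synthesis, and 5 for E-box targets in WT. Other core clock rises in WT were Csnk1e (1.67), Per1 (1.31), Tef (1.15) and Per3 (1.01), and in Bmal1KO Nr1d2 (1.41), Nr1d1 (1.35), Csnk1e (1.35) and Per1 (1.11).

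The largest single changes at 27 °C included H19, an imprinted noncoding RNA (-5.58 ± 0.1 in WT, from 251 ± 27.3 to 4.46 ± 1.53 FPKM), and Angptl4, an inhibitor of lipoprotein lipase (-4.63 in WT and -5.94 in Bmal1KO). WT also had lower Cyp2f2 (-4.41), Prelp (-4.37), Megf6 (-3.97), Rarres2 (-3.96), Anpep (-3.85) and Fmod (-3.78), and higher H2-M1 (3.95), Tnfrsf22 (3.11), Tnfrsf26 (2.95), Klra4 (2.91) and Ptprk (2.83). Bmal1KO had lower Ephx2 (-5.1), Col15a1 (-3.98), Mir6363 (-3.77) and C7 (-3.63), and higher Lgals3 (3.18), Pcdh9 (3.04), Jph1 (3.01), Chaf1b (2.95) and Olfr49 (2.77). The macrophage marker Cd68 rose in both (3.2 and 3.71), from 2.65 ± 1.12 to 30.9 ± 3.87 FPKM in WT, while the macrophage gene Lyz2 fell in WT (-1.3), and the 3 tested macrophage markers as a list gave an adjusted p of 0.64 and 0.931. The ribosomal RNA gene CT010467.1 and AY036118, which overlaps it, had the largest folds in WT (10.59 ± 0.87 and 9.43 ± 0.8), with a wide spread between libraries (CT010467.1 at 5780 ± 3600 FPKM at 27 °C and 957 ± 3350 at 37 °C), and both were listed at 0 in Bmal1KO at 37 °C.

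At 32 °C fewer genes differed from 37 °C: 254 higher and 178 lower in WT (190 and 249 with median-of-ratios scaling) and 234 and 123 in Bmal1KO (163 and 167). With a pseudocount of 0.1 FPKM the totals were 725 and 645. The 32 °C libraries also stood apart in composition: the predicted gene Gm26377, named after its values were seen, held 18.84 to 34.15% of the summed FPKM in each of them, while the top gene held at most 4.46% in any other library. Angptl4 (-3.59 and -3.2) and the collagen gene Col15a1 (-2.99 and -3.23) fell in both. WT had lower Clec3b (-2.88), the interferon-induced Oas2 (-2.55), Rarres2 (-2.5) and Clu (-2.29), and higher Akr1c18 (2.66) and Aldh1a7 (2.39), while Bmal1KO had lower Ephx2 (-3.19), C7 (-2.26), Ear2 (-2.22) and Rbp4 (-1.99). NF-kB and inflammation genes fell in WT (2 of 12, adjusted p = 1.36e-05, and 0.0231 with an estimated correlation, which was 0.0539 without the CT14 libraries at 27 °C) and in Bmal1KO (2 of 12, 7.51e-09, and 0.000314). In Bmal1KO immediate early genes (2 of 8 lower) and adipocyte markers (2 of 3 lower) also held with an estimated correlation, each at 0.0151. The remaining large folds were in small RNAs, such as Mir703 (4.68 and 4.56) and Scarna17 (-6.52 and -6.66).

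The interaction asked whether the response to 27 °C differed between genotypes. The test called 548 genes, 340 positive and 208 negative, and a pseudocount of 0.1 FPKM gave 844. The highest count in random splits of the libraries was 534, too close to 548 to exclude chance. Without the CT14 libraries at 27 °C 361 genes were positive and 218 negative, and 507 of the 548 stayed called. A positive value means a more positive change in Bmal1KO than in WT, and so also arises when a gene falls in WT alone. H19 (5.57 ± 0.14), Megf6 (3.97), Anpep (3.43), Fmod (3.39), Mmp3 (3.32), Col23a1 (3.21), Mgp (3.01) and Grem1 (2.94) led the positive side. H19 stood near the floor in Bmal1KO at both temperatures (1.41 ± 0.367 and 1.49 ± 0.79 FPKM). Ephx2 (-4.77 ± 0.05), Aldh1a7 (-4.23), H2-M1 (-3.73), Saa3 (-3.38), Ear2 (-2.69), Tnfrsf26 (-2.56) and Akr1c18 (-2.5) led the negative side. Immediate early genes had 3 of 8 negative (adjusted p = 3.88e-06, and 0.00113 with an estimated correlation), with Junb at -1.6. Contractile and YAP targets had 5 positive and 1 negative of 10 (0.000137, and adjusted p = 0.0787 with an estimated correlation). The clock genes Bhlhe41 (-1.82), Ciart (-1.39), Bhlhe40 (-1.24), Per2 (-1.21) and Tef (-1.03) had negative interactions. Per2 averaged 1.66 FPKM at 37 °C and 3.38 at 27 °C in WT, and 2.98 and 1.84 in Bmal1KO.

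The rhythm tests in AM and PM asked which transcripts follow a 24 h cosine. In WT, clock genes oscillated in both courses at times about 12 h apart by label. Dbp, an output of the clock, had an amplitude of 0.79 ± 0.06 with a peak at CT23.7 in AM and 0.7 ± 0.05 at CT11.6 in PM. Nr1d1 had 0.63 at CT20.3 and 0.62 at CT7.9, Per3 0.54 at CT1.9 and 0.43 at CT13.2, Cry1 0.33 at CT6.2 and 0.27 at CT17.7, and Arntl 0.35 at CT12 and 0.31 at CT0.5. Of 12 clock genes with an unadjusted p under 0.05 in both courses, 11 peaked 9 to 15 h apart, with a median of 11.3 h. In the test of opposite rhythms 88 genes passed. In list tests of these, chosen after the data were examined, they held 10 of 22 core clock genes (18 adjusted over the list alone; adjusted p = 1.44e-15, one-sided Fisher exact test) and 8 of 15 E-box targets (15 adjusted over the list alone; 2.04e-13). With terms for the 12 h blocks of time labels 17 genes passed, of which 15 were shared with the 88, and without CT00 49 passed. In this fit 1 of 100 random time orders gave as many.

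**Figure D2:**
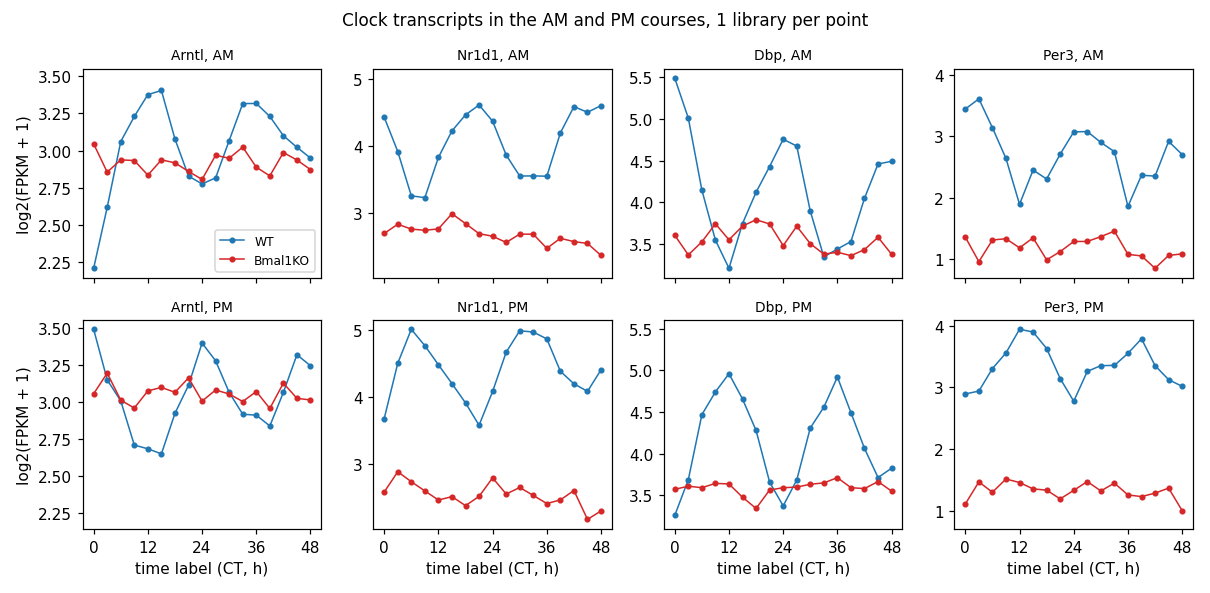
Clock transcript levels, log2(FPKM + 1), against time label (CT, h) in the AM and PM courses of WT and Bmal1KO, 1 library per point. WT Dbp peaks at CT23.7 in AM and CT11.6 in PM, and its range in Bmal1KO is narrow, with 10.7 ± 1.24 FPKM in AM.

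In WT rhythms with the same phase by time label in AM and PM were found in 255 genes, led by the myosin gene Myh9 (0.19 ± 0.03, peak at CT5.2), Nsd3, Pdcd11, Usp22, Kif13b, Myof, Ahcyl1, Cdon and Sf3b3. Of 22 core clock genes Nr1d2 alone was among them (0.15 ± 0.03), and no list passed, the nearest being extracellular matrix genes with 3 of 21 (10 adjusted over the list alone; adjusted p = 0.174). With terms for the 12 h blocks 0 of the 255 passed in limma, with 1103 genes at an unadjusted p under 0.05. The difference between alternate 12 h blocks correlated across genes with transcript length (rho 0.27 in AM and 0.38 in PM). In the courses alone 15 genes passed in AM and 65 in PM, and without CT00 7 and 38. In either course 1 of 100 random time orders gave as many.

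In Bmal1KO most clock genes gave little evidence of rhythm, and many other genes followed a shared 24 h cosine of small amplitude. In the shared fit Dbp had an amplitude of 0.01 ± 0.03 and Arntl 0.01 ± 0.02, neither past the test. In all 1049 genes passed, with a median amplitude of 0.109, a 1.16-fold peak to trough. Genes of smallest p were the ribosomal protein genes Rpl6l (0.16 ± 0.02, CT16.4) and Rpl35a (0.21 ± 0.03, CT17.4), Zmat2 (0.11, CT17.6), and, peaking near CT5, Notch2 (0.17 ± 0.02), the endocytic receptor gene Lrp1 (0.16), the matrix genes Tnxb (0.3 ± 0.04) and Hspg2 (0.17), Ahnak2 (0.17), Hjurp (0.21) and Soga1 (0.19). Ribosomal protein genes (10 of 23, 15 adjusted over the list alone; adjusted p = 0.00011), extracellular matrix genes (8 of 20, 11; 0.00103), contractile genes (4 of 8, 5; 0.0168) and redox genes (6 of 22, 7; 0.0369) were over-represented by one-sided Fisher exact tests. The difference between alternate 12 h blocks correlated across genes with transcript length in AM and in PM (rho 0.32 in each), so these list results are not separate from length or RNA quality. The redox genes were Prdx4, Prdx5, Txn1, Gpx1, Gpx3 and Sod1. Peaks fell between CT3 and CT8 or between CT15 and CT20 for 94.9% of the 1049, and for 85.9% of the 255 in WT.

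With terms for the 12 h blocks 0 of these 1049 passed in limma, with 898 genes at an unadjusted p under 0.05. None of 100 random time orders gave as many, the highest being 16. Opposite rhythms were found in 74 genes, in 0 with the block terms (787 at an unadjusted p under 0.05) and in 0 without the linear time term, and 1 of 100 random orders gave as many. By course, 332 genes passed in AM (0 with the block terms, 928 at an unadjusted p under 0.05) and 2 in PM (2328 at an unadjusted p under 0.05), the latter Aebp1 and Mterf4. Without CT00 PM gave 40, and the scan in PM had most genes at 28 h (758). Genes at an unadjusted p under 0.05 in both courses peaked within 3 h of each other in 62.3% of 493 in Bmal1KO and in 37.3% of 394 in WT, against 25% by chance, and 1 and 23 of 100 random orders gave as large a share. Of genes tested in both genotypes, 84 were in both shared sets (20.9 by chance, p = 2.13e-30, one-sided Fisher exact test), and 82 of them peaked within 3 h of each other. This p treats genes that vary together as independent. Most peaks of both sets also lie in the same windows of time labels. The overlap therefore does not tell a shared rhythm from shared 12 h blocks or transcript length. The genotypes were not shown to differ in these shared rhythms, since the test of the difference averaged over AM and PM called 0 genes.

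**Figure D3:**
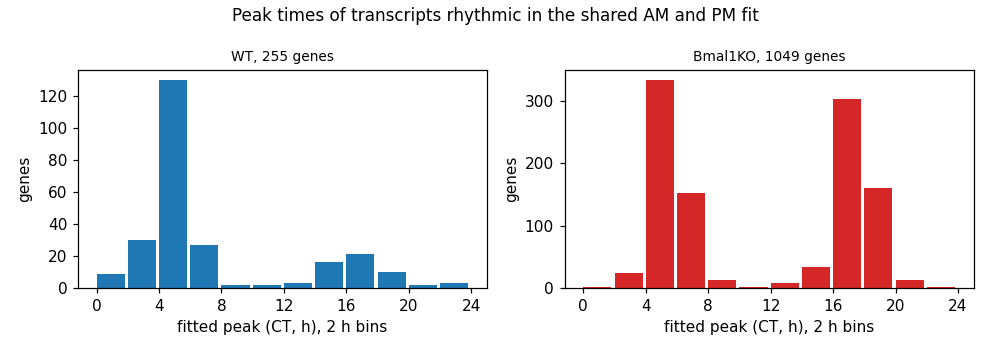
Number of genes against fitted peak time (CT, h, bins of 2 h) for genes called rhythmic in the shared AM and PM fits, 255 in WT and 1049 in Bmal1KO. Between CT3 and CT8 or between CT15 and CT20 lie 94.9% of peaks in Bmal1KO and 85.9% in WT.

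Tests of the difference in rhythm asked whether the genotypes differ. Averaged over AM and PM, 0 genes differed in limma (866 at an unadjusted p under 0.05), an average in which rhythms 12 h apart cancel. In the contrast of AM against PM, chosen after the data were examined, 51 genes differed, led by Dbp (0.73 ± 0.05), Nr1d1 (0.59 ± 0.05), Cry1 (0.33), Arntl (0.32), Nfil3 (0.24), Nr1d2 (0.38) and Per3 (0.45). At 37 °C 25 genes differed, with Dbp at 0.77 ± 0.07 and Arntl at 0.46 ± 0.05. With terms for the 12 h blocks 17 and 5 genes differed. Without CT00 the counts were 23 and 40, and without the Bmal1KO libraries at CT08 and CT16 to CT22 the count at 37 °C was 14.

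At 37 °C WT clock genes again oscillated, with Dbp at 0.7 ± 0.04 (peak at CT2.1), Nr1d1 at 0.68 ± 0.05 (CT23.1) and Arntl at 0.42 ± 0.03 (CT14.6). At 32 °C Dbp had 0.29 ± 0.04 (CT21.5) and Nr1d1 0.28 ± 0.04 (CT16), and at 27 °C Dbp had 0.15 ± 0.1 and Nr1d1 0.07 ± 0.06, neither past the test. The WT fits at 27 °C include the library labelled CT14, which lay at the level of Bmal1KO. These 2 amplitudes are not given without it, so they do not show a loss of rhythm. In WT 472 genes passed at 37 °C, 158 at 32 °C and 0 at 27 °C (930 at an unadjusted p under 0.05 in limma). In Bmal1KO 175, 465 and 161 passed, and no core clock gene was among them. At 37 °C the difference between alternate 12 h blocks correlated across genes with transcript length (rho -0.38 in WT and 0.29 in Bmal1KO). In the scan of periods, more genes passed at other periods in some courses: 690 at 22 h in WT and 2680 at 36 h, the longest period scanned, in Bmal1KO at 37 °C, 490 at 22 h in Bmal1KO at 32 °C and 243 at 26 h in Bmal1KO at 27 °C. Among the genes of smallest p in Bmal1KO, peaking near CT5, were the splicing factor gene Srsf1 (0.2 ± 0.03 at 37 °C and 0.22 ± 0.02 at 32 °C) and the cyclin gene Ccnl2 (0.44 ± 0.04 at 32 °C and 0.39 ± 0.05 at 27 °C). With terms for the 12 h blocks the WT counts became 8, 5 and 0 and the Bmal1KO counts 0, 0 and 0, with 536, 846 and 283 genes at an unadjusted p under 0.05 in Bmal1KO. Without CT00 the WT counts were 732 at 37 °C and 102 at 32 °C. Without the CT14 libraries 605 genes passed in Bmal1KO and 2 in WT at 27 °C, and without CT08 and CT16 to CT22 35 passed in Bmal1KO at 37 °C. In those 5 libraries values correlated across genes with transcript length (rho -0.27 to -0.49). Values of similar size were found in WT at 37 °C at CT24, CT26 and CT30 (-0.36, -0.35 and -0.38) and in WT PM from CT12 to CT21 (-0.31 to -0.35) and CT24 to CT30 (0.28 to 0.38), and in Bmal1KO AM at CT18 (-0.27), Bmal1KO PM at CT12 (-0.3) and CT33 (0.28) and Bmal1KO at 37 °C at CT42 and CT46 (0.29 and 0.32), among others, and the counts were not recomputed without these. For Bmal1KO at 37 °C 2 of 100 random orders gave as many genes as the real order.

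**Figure D4:**
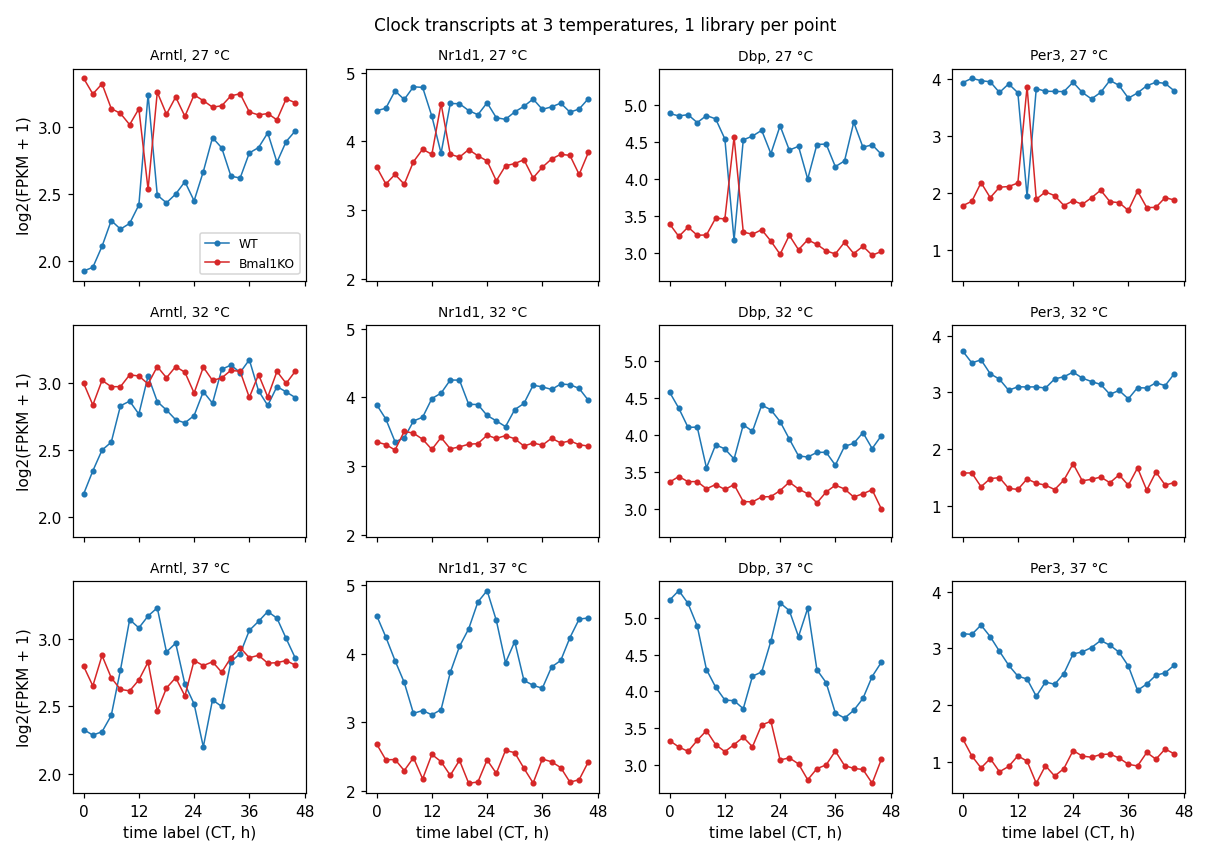
Clock transcript levels, log2(FPKM + 1), against time label (CT, h) at 27, 32 and 37 °C in WT and Bmal1KO, 1 library per point. The WT amplitude of Dbp is 0.7 at 37 °C and 0.29 at 32 °C, and the libraries labelled CT14 at 27 °C lie at the level of the other genotype.

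Fitted over the tested clock genes, the WT period was 24.5 ± 0.57 h at 37 °C (jackknife SE) and 21.75 ± 0.35 h at 32 °C, or 22.75 h at 32 °C without the linear time term. The ratio of rates per 10 °C, Q10, was 0.788 ± 0.045, from 2 temperatures. At 27 °C the best period lay at the edge of the grid and is undefined, with the CT14 library included, and with a quadratic time term it was 25.25 ± 13.05 h. In AM and PM the WT period was 23.75 ± 0.49 and 24 ± 0.49 h. In Bmal1KO the period was undefined at 37 °C and had an SE between 3.43 h in PM and 26.72 h at 32 °C elsewhere. Without the linear time term it was 24 ± 1.77 h in AM, 26 ± 1.99 h in PM, 24 ± 29.51 h at 27 °C and 26.5 ± 12.69 h at 32 °C. It was undefined at 37 °C in that setting. With a quadratic term it was 25.25 ± 2.26 h in AM, 25.75 ± 2.48 h in PM, 26.75 ± 4.08 h at 27 °C and 28 ± 6.48 h at 37 °C. At 32 °C it was then undefined. With the smaller set of clock genes it was undefined in AM and at 32 and 37 °C, 26.75 ± 4.26 h in PM and 25.75 ± 2.38 h at 27 °C.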

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

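The tests of 12 h blocks, of a free-running rhythm, of the CT14 libraries, of a batch in 1 series, of body position and of p53 activity, and the rhythm difference in the contrast of AM against PM, were chosen after the results were seen. The random splits and the test of transcript length were planned.

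An interaction test called a difference between the genotypes in the response to 27 °C for 548 genes, while a random split called 534. Among clock genes the interaction was -1.82 for Bhlhe41, -1.39 for Ciart, -1.24 for Bhlhe40, -1.21 for Per2 and -1.03 for Tef (log2). The largest positive values were 5.57 for H19, 3.97 for Megf6, 3.43 for Anpep, 3.39 for Fmod, 3.32 for Mmp3, 3.21 for Col23a1, 3.01 for Mgp and 2.94 for Grem1. H19 stood near the floor in Bmal1KO at both temperatures. The largest negative values were -4.77 for Ephx2, -4.23 for Aldh1a7, -3.73 for H2-M1, -3.38 for Saa3, -2.69 for Ear2, -2.56 for Tnfrsf26 and -2.5 for Akr1c18.

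The rhythm differed between the genotypes, by a test of the difference, for 25 genes at 37 °C and for 51 genes in the contrast of AM against PM. At 37 °C the amplitude of the difference was 0.77 for Dbp, 0.68 for Nr1d1, 0.46 for Arntl and for Tef, 0.4 for Npas2, 0.38 for Nr1d2, 0.35 for Per3 and 0.3 for Cry1.

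In random splits of the same libraries, 1 of 100, the real grouping, called as many genes in each of the 7 level comparisons. Libraries of a course may share a culture or preparation, so the splits do not exclude chance differences between cultures. The real and the highest other counts were 1935 and 248 for genotype in AM and PM and 1608 and 53 in the temperature series. For the interaction they were 548 and 534, a margin too small to exclude chance. For 32 °C they were 432 and 35 in WT and 357 and 23 in Bmal1KO, and for 27 °C 1773 and 268 and 1533 and 71. For the rhythm difference the real and the highest other counts were 25 and 1 at 37 °C, and 51 and 0 in the contrast of AM against PM. The random groups mix the genotypes, whose levels differ, and this changes the spread in each group. These splits therefore cannot exclude chance for the rhythm differences. For the difference averaged over AM and PM, with 0 calls, 100 of 100 splits gave as many, and the highest other count was 6244. In mixed groups a level difference between the genotypes can enter as a rhythm. Whether it did so in that split was not tested.

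In Bmal1KO 1049 genes followed a shared 24 h cosine in AM and PM, with 94.9% of peaks (85.9% of the 255 in WT) near the middle of the 12 h blocks of time labels. A free-running rhythm with the phase relation of the WT clock genes, of which 11 of 12 peaked 9 to 15 h apart, was not decided. Of 493 genes at an unadjusted p under 0.05 in both courses, 62.3% peaked within 3 h, a share reached in 1 of 100 random orders. Its 95% exact binomial interval, 57.8 to 66.6, treats genes that vary together as independent. The share met the bound set against such a rhythm, but it was adopted after another had been seen and partly restates the pattern. At an unadjusted p under 0.01 it was 79.4%, reached in 12 of 100 orders that left a median of 1 gene. In WT, whose clock genes did run apart, 37.3% of genes peaked within 3 h and 22.8% peaked 9 to 15 h apart. Shares over all such genes therefore did not show the rhythm of the clock genes even there. Sets of harvest, extraction or library making in 12 h blocks stay open: with block terms 22% kept an unadjusted p under 0.05 (50% of simulated cosines, 5% by chance) and 0 stayed called (74 of the simulated), as the median amplitude fell from 0.109 to 0.0581 and its SE rose from 0.0237 to 0.0425. The simulation used the amplitudes fitted to genes selected for this cosine, so its 50% may be too high. The 22% passed the bound of 20% set against this explanation, but its 95% exact interval, 19.5 to 24.7, includes 20, and the interval was asked for only after the 22% was seen. Transcript length or RNA quality also stays open, with rho 0.32 in AM and in PM (0.27 and 0.38 in WT). At 27, 32 and 37 °C rho was 0.06, -0.07 and 0.29 (0.09, -0.16 and -0.38 in WT). The -0.07 meets the planned bound of a change in sign, which was wrong because it covered 5 courses for a pattern of 2. A cellular rhythm without Bmal1 remains untested against these explanations.

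The WT and Bmal1KO libraries with the label CT14 at 27 °C each lay at the level of the other genotype. Over 1364 genes that differ, their median position, from 0 (own group) to 1 (other group), was 0.995 for the library labelled WT and 0.998 for that labelled Bmal1KO, and that of the other 46 libraries was -0.02 to 0.02. A mixture of both genotypes was argued against, as it needs positions between 0.2 and 0.8. A candidate explanation is that the labels of the pair were exchanged, during handling or in the deposited table. Both positions met the bound set for an exchange, at least 0.8, and no biological explanation was tested. The libraries were kept under their labels, so each 27 °C course includes 1 library at the level of the other genotype. Without the pair, the genotype contrast in the temperature series gave 774 higher and 907 lower genes, against 735 and 873 with it.

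Levels differed between the genotypes for 1935 genes in AM and PM. A batch of libraries in 1 of the series was argued against, as 99.3% of the genes called kept their sign in the temperature series. Cell preparations from different body positions may contribute, as 46.2% of 26 Hox genes were called against 14.5% of all genes (p = 0.000114, one-sided Fisher exact test), 11 lower, such as Hoxc10 (-5.23), Hoxa10 (-5.1) and Hoxb9 (-4.77), and Hoxb2 higher (2.14). Different p53 activity of the preparations may also contribute, with a median of 2.25 for the p53 targets (log2). Loss of Bmal1 itself is in the design and stays open, since the number of cell preparations per genotype is not given.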

How the results depend on the processing

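The settings without the CT14 libraries, without the WT AM CT36 library, without 5 Bmal1KO libraries at 37 °C, with 12 h block terms, and in the contrast of AM against PM were chosen after the results were seen. Of the values under other settings that answer a comparison, 164 stayed the same, 59 moved, 4 became stronger and 16 weaker. These values are counts, periods and shares, for which a reversal was not scored. A change of direction within a stable total therefore counts as the same. For named genes, levels gave 2508 the same, 26 stronger and 10 weaker, and rhythms 2904 the same, 22 stronger and 108 weaker. Except where stated, the cause of the changes below was not tested.

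Total level counts stayed within 1.5 times except with a pseudocount of 0.1 FPKM, which gives low genes larger folds: 725 for 32 °C in WT, 645 in Bmal1KO and 844 for the interaction. Median-of-ratios scaling moved the split at 27 °C more than the total, and turned the majority from higher to lower. In WT it went from 1089 higher and 684 lower to 604 and 997, and in Bmal1KO from 1001 and 532 to 573 and 811. With the time label as a block, genotype gave 931 higher and 1002 lower genes in AM and PM and 730 and 866 in the temperature series. Deviations from the course means correlated little between courses by time label (medians 0.02 to 0.05 and 0.01 to 0.07), and the own label gave the highest correlation in 12 of 102 and 33 of 360 cases (6 and 15 by chance). The same label gave the higher median in all 6 and 15 pairs of courses, so a weak link by label is present. With an estimated correlation in camera, the number of lists past the threshold was 1 for genotype in AM and PM and 0 in the temperature series, 1 for 32 °C and 1 for 27 °C in WT, 3 and 2 in Bmal1KO, and 1 for the interaction.

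With terms for the 12 h blocks, rhythm counts in WT were 3 in AM, 3 in PM, 5 at 32 °C, 8 at 37 °C, 0 shared by AM and PM, 17 opposite and 6 shared by the temperatures. In Bmal1KO they were 0 in limma in AM, PM, 27 °C, 32 °C and 37 °C, shared and opposite between AM and PM, and shared by the temperatures (928, 658, 283, 846, 536, 898, 787 and 522 at an unadjusted p under 0.05). The differences between genotypes were 5 at 37 °C and 17 opposite. For the shared rhythms in Bmal1KO the median SE rose with these terms as well, so part of the loss there is one of precision.

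Without the CT00 libraries the counts were 7, 38, 102 and 732 in WT AM, PM, 32 °C and 37 °C, 49 opposite in WT, 40 in Bmal1KO PM, and 40 and 23 for the differences at 37 °C and opposite. Without the linear time term they were 17, 1 and 244 in WT PM, 27 °C and 32 °C, 46 opposite and 1373 shared by the temperatures in WT, 199 and 206 in Bmal1KO AM and PM, 0 opposite in Bmal1KO, and 12, 3 and 20 for the differences at 37 °C, in AM and PM, and opposite, and the WT period at 32 °C was 22.75 h. With a quadratic time term they were 1135 in WT at 37 °C and 39 and 384 in Bmal1KO PM and 37 °C.

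With no filter on low values, which adds genes to the adjustment, they were 43, 77 and 278 in WT PM, 32 °C and 37 °C, 147 shared and 55 opposite in WT, 98, 0 and 64 in Bmal1KO AM, PM and 27 °C, 15 opposite in Bmal1KO and 22 for the opposite difference. A cosine fitted to ranks gave 0 in AM and in PM in both genotypes, and 72 and 96 in Bmal1KO at 27 and 37 °C. Median-of-ratios scaling gave 41 in WT PM, 26 in Bmal1KO PM and 45 opposite in Bmal1KO.

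Without the CT14 libraries 2 genes passed in WT and 605 in Bmal1KO at 27 °C, and 1821 in Bmal1KO over the temperatures. Without 5 Bmal1KO libraries at 37 °C 35 passed in that course and 14 for the difference. The genotype difference in AM and PM was 51 in the contrast of AM against PM. With genes at p under 0.01, the share peaking within 3 h was 44.1% in WT and 79.4% in Bmal1KO between AM and PM, and 58.6% and 95.8% between 37 °C and AM, and 27, 12, 13 and 8 of 100 random orders gave as large a share. The lowest depth, 3.31 M reads in the WT AM CT36 library, limits genes near 1 FPKM there.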

Other observations

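The tests of step against cosine shapes and of peak times given here were chosen after the results were seen.

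Some of the genes of smallest p over the temperature courses peaked near CT5 in both genotypes. Over the 3 temperatures the cyclin gene Ccnl2 had an amplitude of 0.44 ± 0.03 in Bmal1KO and 0.35 ± 0.03 in WT, Clk1, which encodes a kinase of splicing factors, 0.49 ± 0.04 and 0.3 ± 0.04, and Rsrp1 0.48 ± 0.04 and 0.29 ± 0.03. Clasrp (0.32 ± 0.03) and Srsf1 (0.22 ± 0.02) were among the smallest p in Bmal1KO. In all 1186 genes passed in Bmal1KO and 598 in WT, and with terms for the 12 h blocks 0 (522 at an unadjusted p under 0.05 in limma) and 6. Without the CT14 libraries Bmal1KO gave 1821.

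In Bmal1KO the genes of the shared AM and PM rhythm were first compared with a step of the 12 h blocks against a cosine of free phase. The step was better for 24.4, 23.7 and 33.8% of genes at 27, 32 and 37 °C, which by the criterion set for it went against an origin in blocks. That comparison was replaced because the cosine has 1 more parameter than the step. With equal parameters the step was better for 51.6% in AM and 51.7% in PM, where simulated cosines gave 25.3 and 27%, and for 53.7, 50 and 64.3% at 27, 32 and 37 °C, where they gave 38.6, 38.9 and 39.1%. In the mean profile of these genes, changes across block edges were 3.5 and 5.12 times those within blocks in AM and PM, and 1.62 and 1.82 times in simulated cosines. At 27, 32 and 37 °C they were 1.43, 1.57 and 1.99 times, and 1.2, 0.895 and 1.36 times in simulated cosines. The simulated noise was independent between genes, while deviations of real libraries can be shared across genes. The ratios of real and simulated profiles are therefore not directly comparable. The last comparison, with block terms beside the cosine, is the one weighed above. The free-running rhythm was first tested by the share of genes peaking 9 to 15 h apart, 13.8% in Bmal1KO. That share decided nothing, since WT gave 22.8%, also under the 25% of chance, and 83 of 100 random orders in Bmal1KO gave as large a share. It was replaced, after its values were seen, by the share within 3 h. At an unadjusted p under 0.01 that share was 79.4%, and 12 of 100 random orders gave as large a share.

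The lipase gene Lpl fell at 27 °C in WT by 3.44 ± 0.1 and in Bmal1KO by 2.5 ± 0.1, beside its inhibitor Angptl4 (-4.63 and -5.94). The glutathione peroxidase gene Gpx3 fell in WT by 3.43 ± 0.07, with an interaction of 2.63 ± 0.09. In the Bmal1KO course at 37 °C, Lrp1 stood at 172 FPKM at CT08 and at 226, 204, 150 and 188 from CT16 to CT22, and at 314 to 467 in the other libraries.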
